A study of Homo sapiens with 2 samples.

How the data were processed

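Total RNA from 2 cultures of the PLC/PRF/5 line was hybridised to Affymetrix U133 arrays, 1 array per group. Groups were taken from the source names in the labels: differentiated cells and chemoresistant hepatospheres. RNA was isolated with Trizol and labelled with biotin, per the labels' protocols. The deposited values are intensity values, 1 MAS5 signal per probe set on a linear scale, and MAS5 is named in the submitters' processing notes. This method subtracts background and mismatch probe brightness and scales each array globally, which makes weak signals noisy and sets the bulk of genes equal between arrays. Its version and scaling target are not given in the sources used here. In the values themselves the 2% trimmed mean was 500.1 on both arrays, median signals were 70.6 in differentiated cells and 84.1 in hepatospheres, and no detection calls were used. No replicate, and so no spread between cultures or arrays, can be computed, and the number of arrays limits the precision of every value.

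Probe sets were named through GEO's annotation of the array. Of 54675 probe sets, 62 were control probe sets, 41091 paired with 1 gene symbol, 1801 paired with several and were not named, and 11721 were unnamed here. Gene identifiers of 41037 were matched to a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. That table was used only for names and gene order, because the array annotation names no genome build, and no coordinates are given. Each of 19775 gene symbols was represented by its probe set with the highest mean log2 signal. Signals were kept as deposited by the authors. The floor was the higher of the 50th percentiles of signal of the 2 arrays, 84.1. A gene entered when it reached the floor on at least 1 array, and a signal below the floor was set to it before log2 was taken, so that the fold of such a gene is a lower bound. Differences are log2 signal in hepatospheres minus differentiated cells, and genes at least 2-fold and 4-fold apart were counted.

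For 44 gene lists fixed before the data were examined, the median difference of the members was set among 10000 random lists of the same size, matched on mean signal in 20 bins, for lists with at least 5 members measured. Genes named in the text were chosen by a rule fixed at the same time. It takes the 12 highest and 12 lowest genes above the floor on both arrays whose probe sets go the same way. It adds, under the same condition, the 6 brightest genes seen above the floor on each array alone. Without that condition it adds up to 4 members with the largest differences from each list and 12 genes named in any case. Exceptions are marked as chosen after their values were seen. Medians in windows of 50 neighbouring genes, stepped by 10 and taken relative to the all-gene median, were compared with 1000 shuffles of gene positions, and overlapping windows above the 95th percentile of the shuffled highest window (0.50) or below the 5th percentile of the shuffled lowest (-0.51) were merged into runs. Control probe sets were compared between arrays, and 3' to 5' signal ratios were taken for ACTB, GAPDH and the poly(A) controls.

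Both procedures were tested on simulated data. Over 12766 genes, lists of 20 genes shifted by 0.3, 0.6 and 1 on the log2 scale were found in 41, 88 and 100 of 100 simulations, and 3 of 100 lists without a shift lay outside the central range. Differences were permuted among genes beforehand, so lists of genes that vary together were not covered. A stretch of 100 genes shifted up by 0.6 was found in 20 of 20 simulations over 12747 genes in order. Without a shift, 2 of 20 had a window above the upper threshold. Neither downward shifts nor the lower threshold were simulated, so the lower runs were not covered. Alternatives were median centring, quantile normalization, loess on signal (span 0.3), floors at the 40th and 60th percentiles, no floor, log2 of signal plus floor, the mean over a gene's probe sets, leaving out probe sets whose names mark shared or cross-matching sequence, other window sizes, and, added after seeing the data, scaling to the poly(A) controls and leaving out genes inside shifted runs. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.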

Results

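Gene expression was measured in PLC/PRF/5, an established human hepatocellular carcinoma cell line, on 2 Affymetrix arrays of 54675 probe sets each. One array held RNA from chemoresistant hepatospheres, which are tumour spheroids kept under cisplatin, a platinum drug that crosslinks DNA, together with doxorubicin, an anthracycline that poisons topoisomerase II. The other held RNA from differentiated cells, which came from spheroids that were given fetal bovine serum and left to attach. Each group had 1 array and no replicates, so no difference was tested and none carries an error. Spheroid growth, serum and attachment differed between the 2 arrays at once, and the labels do not say whether the spheroids behind the differentiated cells had been drug-treated, so it is not known whether drug exposure differed too. Values are MAS5 signals on a linear scale, and a difference is of hepatospheres relative to differentiated cells. A gene below the floor of 84.1 signal units on 1 array has only a lower bound, given as "at least".

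The comparison asks which genes set drug-resistant hepatospheres, a culture used to enrich tumour-initiating cells, apart from their differentiated counterparts. CD47, the surface protein that signals to phagocytes not to engulf a cell, read 2015 in differentiated cells and 10375 in hepatospheres, a 5.15-fold higher signal. That size depended on the probe set. Without probe sets whose names mark shared or cross-matching sequence, CD47 stood at 0.40 on the log2 scale on the brightest one left. Another of those left rose from 52.6, below the floor, to 289. ABCB1, the drug efflux pump P-glycoprotein, stood 15.1-fold higher, at 2888 against 191. Genes of cholesterol synthesis, the hypoxia response, the immediate early response, histones and MHC class I were mostly higher in hepatospheres. Genes of DNA replication and mitosis were lower without exception among the listed members measured, and part of the DNA repair and NRF2 antioxidant genes were lower too.

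Of 12766 genes at or above the floor on at least 1 array, 1601 were at least 2-fold higher in hepatospheres and 1127 at least 2-fold lower. At 4-fold these numbers were 382 and 134. At or above the floor on 1 array only were 1262 genes in hepatospheres and 441 in differentiated cells. Signals of the 11063 genes above the floor on both arrays correlated across genes with r = 0.89, where genes are not independent replicates. The higher genes made up 58.7% of those 2-fold apart with the deposited scaling and 6.47% (399 higher, 5764 lower) when the arrays were scaled to their poly(A) control RNAs. That scaling, chosen after the controls were seen, shifts the median of all genes by -0.97 on the log2 scale, so the directions given here hold relative to the bulk of genes and not per unit of control RNA. Sizes also depended on the probe set: with the mean over a gene's probe sets, ABCB1 stood at 2.66 on the log2 scale instead of 3.92, CD47 at 1.44 instead of 2.36, AXL at 1.85 instead of 3.57 and ID4 at -2.95 instead of -5.08.

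**Figure D1:**
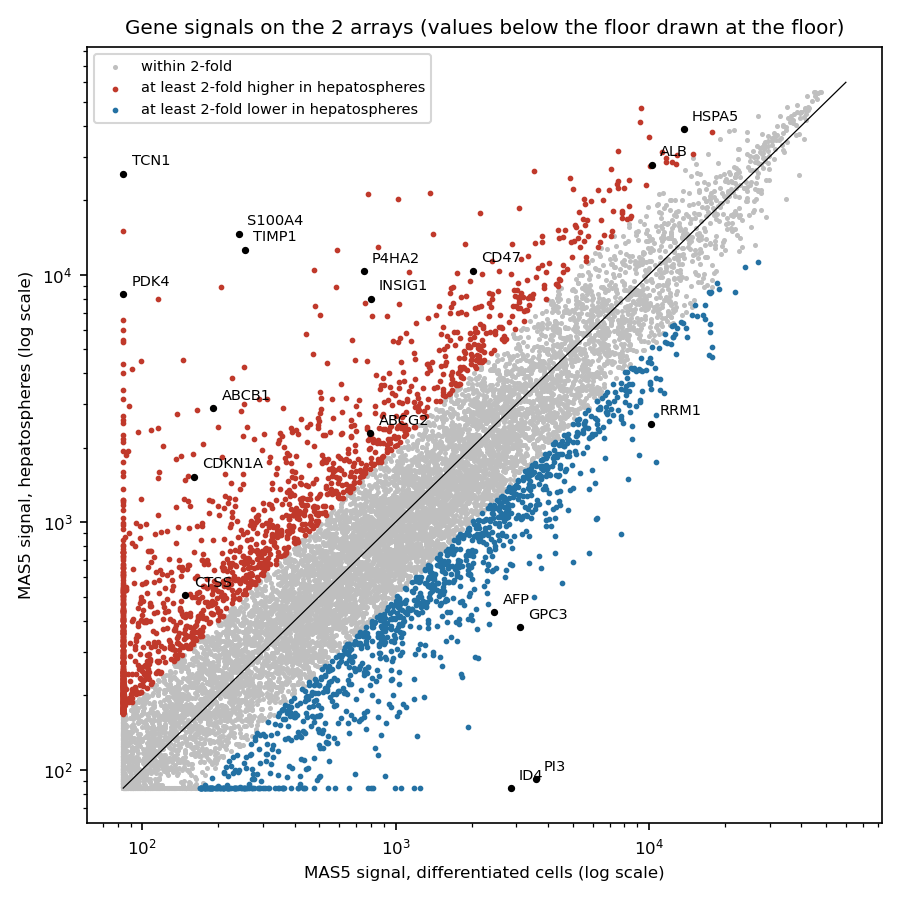
MAS5 signal of each gene in differentiated cells (x axis, log scale) and hepatospheres (y axis, log scale), 1 array each, with signals below 84.1 drawn at that floor and the line marking equal signals. The 1601 genes at least 2-fold higher in hepatospheres are red and the 1127 at least 2-fold lower are blue, with CD47 at 2015 and 10375 and ABCB1 at 191 and 2888 among the labelled genes.

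Genes measured above the floor on both arrays were ranked where all probe sets of a gene went the same way. Among these the neuronal protease inhibitor SERPINI1 was furthest apart, 69.0-fold higher in hepatospheres. S100A4, a calcium-binding protein linked to cell motility, was 60.8-fold higher, and TIMP1, an inhibitor of matrix metalloproteinases, 49.8-fold higher. The gut peptide gene CCK (45.5-fold), the adhesion molecule NRCAM (45.4-fold), the intestinal keratin KRT20 (43.8-fold), the cytokine TNFSF15 (33.4-fold), the adhesion molecule CEACAM1 (31.3-fold) and the galectin LGALS1 (27.2-fold) followed. ABCA8, BEX5 and PTGS2, the last encoding cyclooxygenase 2, were 23.9-fold, 22.2-fold and 21.8-fold higher. In the other direction, the elastase inhibitor PI3 was 39.2-fold lower and EDN1, the precursor of endothelin 1, 13-fold lower. IL17D, NMRAL2P and the long noncoding RNA UCA1 were 9.64-fold, 8.87-fold and 8.63-fold lower. GPC3, FOXQ1, WFDC21P, DDC, MGLL, NEIL3 and SCARA5 were between 7.45-fold and 8.26-fold lower. Some of these sizes depended on the probe set or the floor. With the mean over probe sets NRCAM stood at 3.76 on the log2 scale instead of 5.50. CEACAM1 then stood at 3.83 instead of 4.97, and EDN1 at -2.49 instead of -3.70. CCK, NRCAM, TNFSF15, BEX5 and ABCA8 read only 91.0, 98.5, 88.8, 87.8 and 96.4 in differentiated cells, close to the floor. PI3 and IL17D read 91.3 and 94.2 in hepatospheres, also close to it. With log2 of signal plus floor, CCK stood at 4.59 instead of 5.51 and PI3 at -4.38 instead of -5.29. SERPINI1 then stood at 5.34 instead of 6.11, BEX5 at 3.56 instead of 4.47, ABCA8 at 3.73 instead of 4.58 and IL17D at -2.48 instead of -3.27.

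Some genes were above the floor on 1 array only. TCN1, which encodes a vitamin B12 carrier, read 25631 in hepatospheres and was at least 305-fold higher. CGA, the common subunit of glycoprotein hormones, was at least 178-fold higher. PDK4, the kinase that restrains pyruvate oxidation, was at least 99.2-fold higher, SERPINE2 at least 77.9-fold, LINC01419 at least 71.1-fold and the secretory granule gene CHGB at least 65.1-fold. The opposite held for ID4, an inhibitor of helix-loop-helix transcription factors, at least 33.8-fold lower in hepatospheres. TGM3, CDYL2, SLC25A18, ANO3 and DSEL were at least 14.8-fold, 14.0-fold, 12.5-fold, 11.8-fold and 9.68-fold lower. These bounds hold for the brightest probe set of each gene and the floor of 84.1: with the mean over probe sets PDK4 stood at 4.61 on the log2 scale, CDYL2 at -2.55 and DSEL at -1.85, against 6.63, -3.81 and -3.28, and with the floor at the 60th percentile these 3 genes stood at 5.77, -2.95 and -2.41.

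Gene lists fixed before the data were examined were summarised by the median log2 difference of their members and its percentile among 10000 random lists of the same size and similar signal, as a description of these 2 arrays. Of 42 lists with a percentile, 18 lay above and 4 below the central 95% of random lists, where lists of independent genes would place 2.1 outside. Random lists draw genes independently, whereas members of a list here can vary together, and some lists share members such as ATF3 and AKR1B10. The excess over 2.1 is therefore not calibrated. Every list is given relative to arrays on which the poly(A) control RNAs differed 2.04-fold and the ACTB 3' to 5' ratio differed as well.

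**Figure D2:**
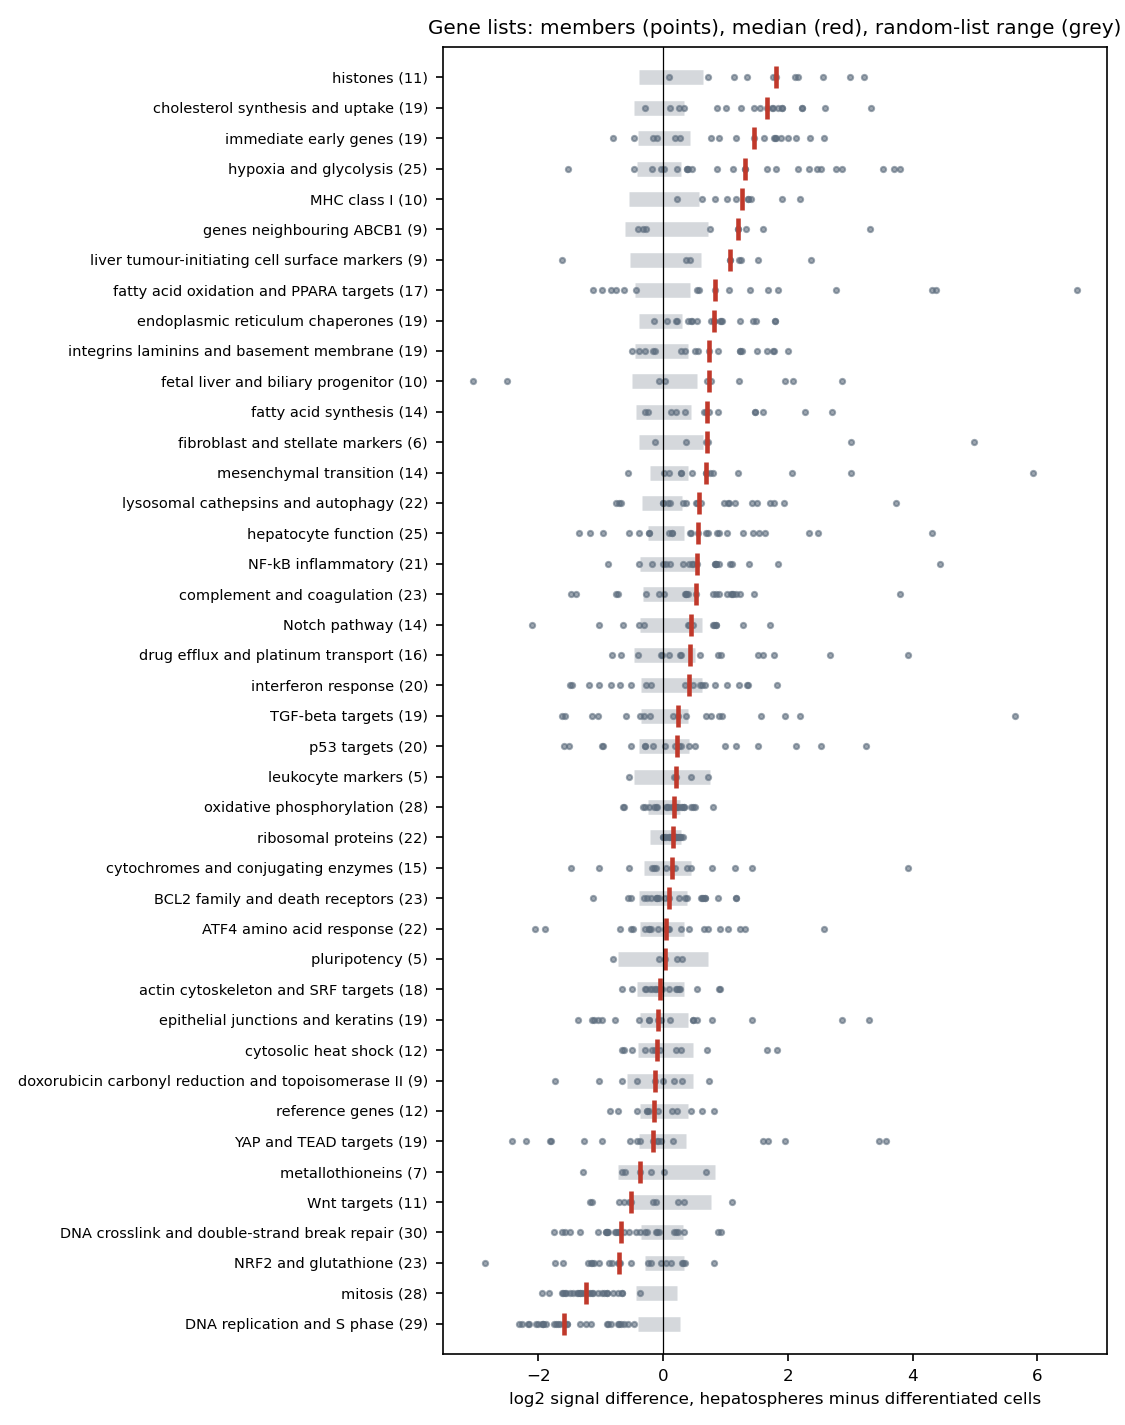
Log2 signal difference, hepatospheres minus differentiated cells (x axis), for the members of 42 gene lists (rows, number of members measured in brackets): grey points are genes, red bars list medians, and grey bands hold the central 95% of the medians of 10000 random lists. Histones (median 1.82) and cholesterol synthesis (1.67) lie furthest to the right, mitosis (-1.23) and DNA replication (-1.59) furthest to the left.

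Markers used to isolate liver tumour-initiating cells were higher in 6 of 9 measured members, lower in 1 and within 2-fold in 2. Their median was 1.07 (percentile 100). All but ALDH1A1, an enzyme gene named after its value was seen (0.43 on the log2 scale), encode surface proteins. Beside CD47, the efflux pump ABCG2 was 2.88-fold higher, the aminopeptidase ANPEP (CD13) 2.37-fold, CD24 2.32-fold with all 6 probe sets higher, and the hyaluronan receptor CD44 2.10-fold at a low signal of 562. CD44 stood at 0.59 on the log2 scale without shared-sequence probe sets (names ending in _s_at or _x_at). The calcium channel subunit CACNA2D1 was at least 3.09-fold lower, a bound that shrank to -0.77 with the floor at the 60th percentile of signals. PROM1 (CD133) and EPCAM lay below the floor on both arrays, at 6.85 and 39.7 in hepatospheres. CTSS, the lysosomal protease cathepsin S, read 148 in differentiated cells and 507 in hepatospheres, 3.42-fold higher. CD47 and CTSS belonged to a separate list of 3 genes whose remaining member was not analysed here, and both were higher (median 2.07). This list was written from knowledge of the study, which may have picked it on these arrays, and is not independent evidence. The size of the CD47 difference depended on the probe set. All 5 that reached the floor were higher, but by between 0.18 and 2.48 on the log2 scale. With shared-sequence probe sets left out, CD47 stood at 0.40 on the brightest one left. A dimmer one stood at 0.18 and another rose from 52.6 to 289, so those left disagreed in size. The marker list then stood at 0.43, which is the value of ALDH1A1. Pluripotency factors showed no common direction, with 0 of 5 measured members 2-fold apart (median 0.03, percentile 53.8), including KLF4 at 0.30, SALL4 at -0.06, MYC at -0.80 and a NANOG signal of 97.8 in hepatospheres.

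Liver identity genes were split. Of 25 measured hepatocyte genes, 8 were at least 2-fold higher, 2 lower and 15 within 2-fold (median 0.57, percentile 99.9). PCK1, the gluconeogenic enzyme, was 19.9-fold higher, the thyroxine carrier TTR 5.62-fold, the apolipoproteins APOA2 and APOH 5.07-fold and 3.09-fold, and albumin (ALB) 2.71-fold, from 10276 to 27887. Fetal liver and biliary progenitor genes went both ways, with 4 of 10 higher and 2 lower (median 0.73, percentile 99.6). The oncofetal genes GPC3 and AFP were 8.26-fold and 5.66-fold lower, whereas the biliary genes SOX9 and KRT7 were 4.24-fold and 7.35-fold higher. The other KRT7 probe set read lower, and without shared-sequence probe sets KRT7 stood at -0.71 and this list's median at -0.39. Complement and coagulation genes were higher in 8 of 23 and lower in 2 (median 0.52, percentile 98.0), led by SERPIND1 (at least 13.9-fold higher) and F10 (2.74-fold), with SERPING1 at least 2.77-fold (-0.61 with the floor at the 60th percentile) and KNG1 2.63-fold lower. Cytochromes and conjugating enzymes were higher in 3 of 15 and lower in 2 (median 0.15, percentile 63.5). Among them CYP1A1, the classic target of the aryl hydrocarbon receptor, was 15.3-fold higher, the receptor gene AHR 2.70-fold higher, CYP3A5 2.22-fold higher and ADH4 2.78-fold lower.

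Drug transport and drug response genes did not differ as a block. Of 16 measured transport genes, 5 were higher and 0 lower by 2-fold (median 0.44, percentile 95.4): ABCB1, ABCA3 (6.42-fold), the copper and platinum importer SLC31A1 (3.44-fold), ABCB4 (at least 3.04-fold, but 0.74 on the log2 scale with the floor at the 60th percentile) and ABCG2. Genes of doxorubicin reduction and its target had 0 of 9 higher and 2 lower (median -0.13, percentile 35.7), with AKR1B10 3.31-fold and CBR4 2.03-fold lower (CBR4 at -0.59 with the mean over probe sets), POR at 0.73 and the doxorubicin target TOP2A at -0.65. NRF2 and glutathione genes were lower in 8 of 23 and higher in 0 (median -0.70, percentile 0), among them OSGIN1 (7.21-fold), SRXN1 (3.04-fold) and the glutathione synthesis subunit GCLM (2.30-fold). Metallothioneins, which bind metals and platinum, had a median of -0.37 over 7 members (percentile 15.7), 1 of them lower by 2-fold (MT1H, 2.43-fold) and 0 higher. Of 20 p53 targets, 5 were higher and 2 lower (median 0.23, percentile 85.9). CDKN1A, the cell cycle inhibitor p21, was 9.58-fold higher, TP53INP1 5.75-fold and GDF15 4.40-fold, the last at 0.70 on the log2 scale without shared-sequence probe sets, while the repair gene DDB2 was 2.99-fold lower. DNA crosslink and double-strand break repair genes were lower in 6 of 30 and higher in 0 (median -0.67, percentile 0.01). The lower ones included FANCI (3.36-fold), EXO1 (3.07-fold), BRCA1 (2.97-fold) and BLM (2.79-fold). The other 24 were within 2-fold, and 6 of the 30 lay above 0. Among these 6 were ERCC1 at 0.93 and ERCC4 at 0.88, named after their values were seen. The BCL2 family and death receptors were mostly within 2-fold, 20 of 23 (median 0.10, percentile 68.6), with BIK and TNFRSF10B 2.26-fold and 2.25-fold higher and HRK 2.18-fold lower. With the mean over probe sets TNFRSF10B stood at 0.80 and HRK at -0.55, HRK stood at -0.16 without shared-sequence probe sets, and BIK at 0.86 with log2 of signal plus floor.

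Proliferation genes were the lists lowest in hepatospheres. Of 29 measured genes of DNA replication and S phase, 20 were at least 2-fold lower and 0 higher (median -1.59, percentile 0). The primase and polymerase genes PRIM1 and POLA1 were 4.94-fold and 4.80-fold lower, the chromatin assembly gene CHAF1B 4.50-fold and UHRF1 4.42-fold. Mitosis genes were lower in 19 of 28 and higher in 0 (median -1.23, percentile 0), with HMMR 3.84-fold, CENPE 3.56-fold, PLK1 3.08-fold and CENPF 3.04-fold lower. Replication-dependent and other histone genes went the other way, 9 of 11 higher and 0 lower (median 1.82, percentile 100). H1-2 was 9.32-fold higher, H2AC6 7.98-fold, H2BC5 5.92-fold and H2BC9 4.46-fold, and 5 of the 11 members lay below the floor in differentiated cells. Of these 11 genes 10 lie in 1 chromosomal run on chromosome 6 described with the windows, so the list and that run are largely the same observation. Immediate early genes were higher in 11 of 19 and lower in 0 (median 1.46, percentile 100), among them ATF3 (6.0-fold), JUN (5.11-fold), KLF2 (4.40-fold) and FOS (at least 4.0-fold).

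Metabolic lists were among the highest. Cholesterol synthesis and uptake genes were higher in 14 of 19 and lower in 0 (median 1.67, percentile 100), with INSIG1 10.1-fold, MSMO1 6.06-fold, the squalene epoxidase SQLE 4.71-fold and TM7SF2 4.67-fold higher. Fatty acid synthesis genes were higher in 5 of 14 and lower in 0 (median 0.71, percentile 99.8), led by ACSS2 (6.54-fold), PNPLA3 (4.82-fold), ELOVL5 (3.03-fold) and SCD (2.78-fold). Fatty acid oxidation genes and PPARA targets were higher in 8 of 17 and lower in 1 (median 0.84, percentile 100), and besides PDK4 the fatty acid carriers CD36 and FABP1 were 20.8-fold and 19.9-fold higher. Without shared-sequence probe sets CD36 and FABP1 stood at 2.65 and 2.88 on the log2 scale instead of 4.38 and 4.31. PDK4 and CD36 lie in the chromosome 7 run described with the windows, so for them the list and that run are the same observation. ANGPTL4, shared with the hypoxia response, was 6.86-fold higher. Hypoxia and glycolysis genes were higher in 14 of 25 and lower in 1 (median 1.32, percentile 100). Collagen prolyl hydroxylases P4HA2 and P4HA1 were 13.8-fold and 7.33-fold higher, the aldolase ALDOC 13-fold and ANKRD37 11.5-fold. Oxidative phosphorylation (median 0.17, percentile 85.6) and ribosomal protein genes (median 0.17, percentile 74.5) had 0 members 2-fold apart of 28 and 22, with UQCRC2 at 0.81, NDUFS3 at -0.64 and RPS16 at 0.32. Reference genes spanned GUSB at 0.81 to TFRC at -0.85 (median -0.15, percentile 16.8), with 0 of 12 2-fold apart.

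Endoplasmic reticulum chaperones were higher in 5 of 19 and lower in 0 (median 0.81, percentile 100). The chaperone HSPA5 (BiP) was 2.82-fold higher, DNAJB9 3.46-fold, MANF 2.72-fold and HERPUD1 3.46-fold, although HERPUD1 stood at 0.53 on the log2 scale without shared-sequence probe sets. The ATF4 amino acid response had 4 higher and 2 lower of 22 (median 0.05, percentile 61.8). ATF3 and DDIT4 (2.5-fold) were higher and ATF5 (4.16-fold) and the amino acid transporter SLC7A5 (3.71-fold) lower. Cytosolic heat shock genes had 2 higher and 0 lower of 12 (median -0.09, percentile 25.7), which were DNAJB1 (3.56-fold) and HSPB1 (3.17-fold). Lysosomal cathepsins and autophagy genes were higher in 9 of 22 and lower in 0 (median 0.58, percentile 99.9), with CTSF at least 13.3-fold, CTSH 3.84-fold and WIPI1 3.27-fold higher beside CTSS.

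Adhesion and matrix genes were mixed. Integrins, laminins and basement membrane genes were higher in 8 of 19 and lower in 0 (median 0.74, percentile 100), with LAMB1 3.99-fold, HSPG2 3.43-fold, ITGB5 3.38-fold and ITGA2 3.17-fold higher. Mesenchymal transition genes were higher in 4 of 14 and lower in 0 (median 0.69, percentile 100). Those 4 were S100A4, fibronectin (FN1, 4.19-fold), ZEB1 (2.29-fold, 0.89 on the log2 scale with the mean over probe sets) and COL3A1 (at least 8.07-fold), and 7 of the 14 were below the floor on 1 array. Epithelial junction and keratin genes had 3 higher and 4 lower of 19 (median -0.09, percentile 27.5), with CLDN4 9.90-fold and MUC1 at least 2.68-fold higher and OCLN 2.56-fold lower, MUC1 and OCLN standing at 0.80 and -0.81 with the mean over probe sets. YAP and TEAD targets split into 5 higher and 5 lower of 19 (median -0.16, percentile 19.8). AXL and NT5E were 11.9-fold and 11-fold higher, whereas AMOTL1 was 5.32-fold and FOXF2 at least 4.58-fold lower. Actin cytoskeleton and SRF targets were all 18 within 2-fold (median -0.04, percentile 47.7), from TAGLN at 0.91 to CORO1C at -0.66. TGF-beta targets had 4 higher and 4 lower of 19 (median 0.25, percentile 88.4), with TGFB1 at least 4.57-fold (0.98 on the log2 scale without shared-sequence probe sets) and TGFB2 3.88-fold higher and SMAD7 3.06-fold lower. Notch pathway genes had 2 higher and 2 lower of 14 (median 0.45, percentile 85.7), and their ligands parted: JAG2 was 3.29-fold higher and JAG1 4.28-fold lower. Wnt targets had 1 higher and 2 lower of 11 (median -0.51, percentile 2.78), namely TBX3 (2.14-fold higher), CCND1 (2.24-fold lower) and PRLR (at least 2.19-fold lower). These calls were not firm: 2 of the 3 TBX3 probe sets read lower and their mean stood at 0.25, CCND1 stood at -0.95 with the mean over probe sets, and PRLR at -0.27 with the floor at the 60th percentile.

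Antigen presentation genes of MHC class I were higher in 7 of 10 and lower in 0 (median 1.27, percentile 100). HLA-B was 4.56-fold higher, HLA-C 3.75-fold, HLA-G 2.66-fold and HLA-F 2.58-fold, and probes for these closely related genes can bind more than 1 of their transcripts. Interferon response genes split, 5 higher and 4 lower of 20 (median 0.41, percentile 88.2), with ISG15 3.56-fold and PSMB9 at least 2.56-fold higher, IFIT3 at least 2.80-fold and BST2 2.74-fold lower, where the bounds of PSMB9 and IFIT3 shrank to 0.50 and -0.63 on the log2 scale with the floor at the 60th percentile. NF-kB inflammatory genes were higher in 5 of 21 and lower in 0 (median 0.54, percentile 98.1), among them PTGS2, NFKB2 (3.57-fold), CXCL3 (2.59-fold) and CFB (2.16-fold). NFKB2 stood at 0.71 on the log2 scale without shared-sequence probe sets, CXCL3 at 0.87 with the floor at the 60th percentile, and CFB at 0.97 after quantile normalization and 0.77 with log2 of signal plus floor.

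Few markers of cells that a tumour culture should not hold reached the floor. Of 5 leukocyte genes that reached it, 0 were 2-fold apart (median 0.22, percentile 54.8), with FCER1G at 0.44 and LYZ at 0.72. LYZ was abundant on both arrays, at 6364 in differentiated cells and 10455 in hepatospheres, and its difference stood at 2.83 without shared-sequence probe sets. Of 3 endothelial genes 0 were 2-fold apart (median 0.16), among them FLT1 at -0.52 and PECAM1 at 0.16, the latter with signals of 3388 and 3787. Fibroblast and stellate markers were higher in 2 of 6 and lower in 0 (median 0.71, percentile 99). These were the matrix proteoglycan LUM, at 1.14 in differentiated cells and 2677 in hepatospheres (at least 31.8-fold), and COL3A1, whereas COL1A1 read 471 and DCN 139 in hepatospheres. The median of this list stood at -0.13 without shared-sequence probe sets and at 2.15 with the floor at the 60th percentile of signals, and 5 of its 6 members were below the floor on 1 array.

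Whether neighbouring genes differed together was examined in windows of 50 genes in chromosomal order. Relative to the all-gene median, the highest window had a median of 0.99 and the lowest -0.80, where the typical extremes of 1000 shuffled gene orders were 0.40 and -0.42. Overlapping windows beyond the shuffled extremes merged into 14 runs, 4 higher and 10 lower in hepatospheres (2 and 5 with windows of 25 genes), holding 1050 of the 12747 placed genes. The longest spanned 200 genes of chromosome 7 from VKORC1L1 to FAM185A and contained ABCB1. Its median was 0.67, 67 of its genes were at least 2-fold higher and 3 lower, and 159 of 200 lay above the all-gene median (79.5%, exact binomial 95% interval 73.2 to 84.9, which treats genes as independent and follows on the choice of the run for its high medians). Among 9 measured genes on the fixed list of ABCB1 neighbours, 5 were higher and 0 lower (median 1.20, percentile 99.9), including RUNDC3B (at 3.32 on the log2 scale), ADAM22 (2.52-fold, 0.79 on the log2 scale with the floor at the 60th percentile) and TMEM243 (2.31-fold). The neighbours CROT, SLC25A40 and DBF4, named after their values were seen, stood at -0.31, -0.41 and -0.28. Without ABCB1 and its listed neighbours the other 190 genes of the run had a median of 0.65. Besides PDK4 and CD36, the run also holds CLDN4, HSPB1, CYP3A5, POR, GUSB and ABCB4. Their higher values in the lists are therefore not independent of the run. CACNA2D1, also in the run, was lower. The stretch directly before the run in gene order, RALA to ZNF92, was lower (60 genes, median -0.54) and holds DDC. Another higher run, HDGFL1 to OR2H4P on chromosome 6 (60 genes, median 0.52), holds the main histone cluster. Its 50 genes outside the fixed histone list had a median of 0.25. They still include histone genes such as H1-3 and H4C4, so the non-histone neighbours were not summarised apart. The lowest runs were PLCXD1 to TASL on chromosome X (70 genes, median -0.62) and MYO7A to SIDT2 on chromosome 11 (120 genes, median -0.55), and 3 further lower runs lay on chromosome 12.

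**Figure D3:**
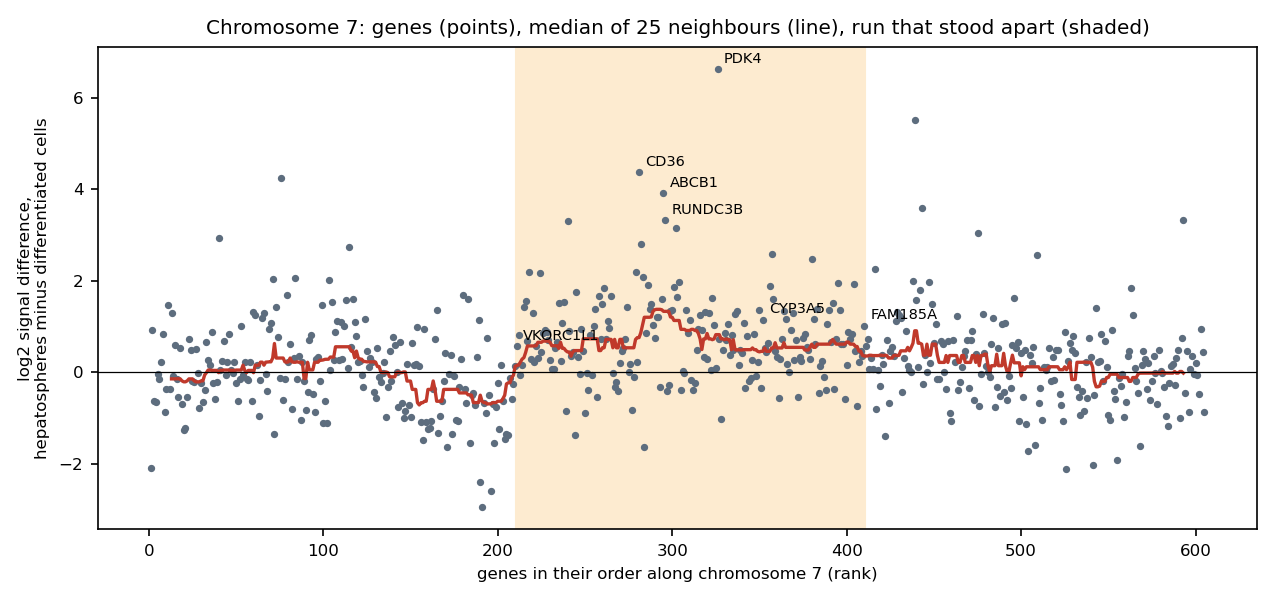
Log2 signal difference, hepatospheres minus differentiated cells (y axis), of each gene of chromosome 7 by its rank in gene order (x axis, not to physical scale), with the median of 25 neighbouring genes as a red line and the run from VKORC1L1 to FAM185A shaded. The run's 200 genes have a median of 0.67, and the 60 genes directly before it a median of -0.54.

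Control probe sets gave the technical differences between the arrays. The 18 probe sets of hybridisation controls, added after labelling, differed by a median of 0.18 on the log2 scale, with an SD of 0.05 across probe sets, a sign that turns when the arrays are scaled to the poly(A) controls. The 24 probe sets of poly(A) control RNAs, added before labelling, read 2.04-fold higher on the hepatosphere array (median 1.03). The signal ratio of 3' to 5' probe sets was 1.48 in differentiated cells and 2.64 in hepatospheres for ACTB, and 0.99 and 1.04 for GAPDH. Different probe sets of the same gene disagreed in sign for 35.9% of the 6228 genes with several, and log2 differences of probe sets of a gene had a pooled SD of 0.51 over the 5206 genes with several above the floor on both arrays.

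**Figure D4:**
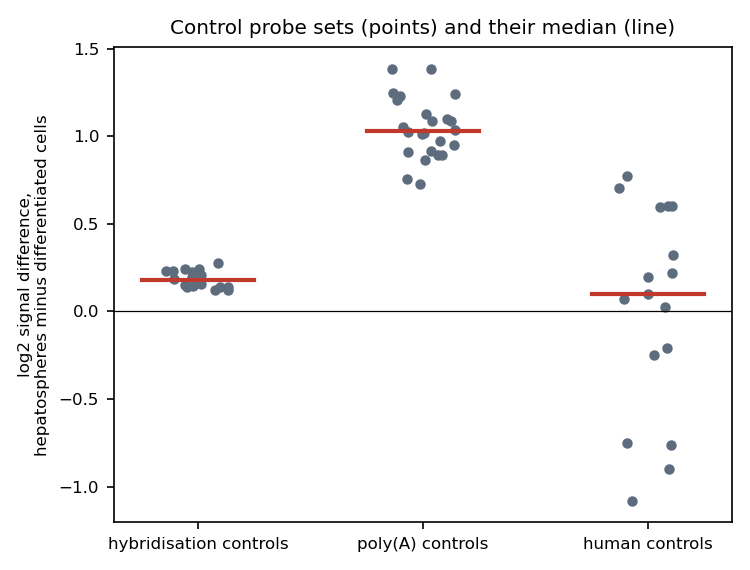
Log2 signal difference, hepatospheres minus differentiated cells (y axis), of hybridisation, poly(A) and human control probe sets (x axis); points are probe sets and red lines medians. The medians are 0.18, 1.03 and 0.10.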

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

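The tests of the poly(A) control pattern were chosen after its values were seen. The 24 poly(A) control probe sets, which belong to no gene comparison, read higher on the hepatosphere array by a median of 1.03 on the log2 scale. Hybridisation controls differed by only 0.18, which argues against a difference in hybridisation or array scaling. A loss of 5' sequence in the cellular RNA stays open, since the 3' to 5' ratio was higher on the hepatosphere array by 0.83 for ACTB but only 0.07 for GAPDH. For the poly(A) controls dap, thr, phe and lys, added before labelling, this ratio was higher by 0.30, 0.16, 0.06 and 0.01. Those values cannot show a loss in cellular RNA before the controls were added. Less cellular mRNA for each unit of control RNA stays open too. Scaled to these controls, the median of all genes stands at -0.93, which restates the control difference and tests nothing. With 1 array per group a smaller RNA input cannot be told apart from a smaller mRNA share of total RNA in the drug-treated spheroids. That biological difference was not tested.

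The ACTB control probe sets differed between the arrays in their 3' to 5' ratio by 0.83 on the log2 scale, against 0.07 for GAPDH. Among 5342 probe sets at or above the floor that pair with several genes or with none named here, 118 were at least 4-fold higher in hepatospheres and 34 at least 4-fold lower, signals that no gene comparison uses.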

How the results depend on the processing

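Scaling to the poly(A) controls and leaving out genes of the shifted runs were chosen after the data were seen. No paired analysis was possible because each group has 1 array. A value without replicates was taken as moved when it differed by over 1.5-fold. Poly(A) scaling shifts the all-gene median by -0.97 on the log2 scale, and signals at the floor less, so list medians and named genes are counted here relative to that median. Of 483 list medians under the alternatives 476 did not move, and 1778 of 1940 values of named genes did not. Counted that way, 136 of 162 named genes at least 2-fold apart stayed so under every alternative that gave a value. A list median smaller than 1.5-fold can vanish without counting as moved, and list percentiles were not recomputed, so the count of list medians says little about their stability. With no floor, 4232 genes were 2-fold higher and 2431 lower, 1732 and 681 at 4-fold, and the mesenchymal and fibroblast lists had medians of 1.28 and 2.12, since weak signals then enter as deposited. The fibroblast list stood at 2.15 with the floor at the 60th percentile. With log2 of signal plus floor, 68 genes were 4-fold lower. Without shared-sequence probe sets the fetal liver list reversed to -0.39, the fibroblast list to -0.13 and KRT7 to -0.71, while the tumour-initiating marker list stood at 0.43 and the list holding CD47 and CTSS at 1.09. The cause was not tested. Scaled to the poly(A) controls, 399 genes were 2-fold higher and 5764 lower, 120 and 1098 at 4-fold, since the scaling lowers all hepatosphere signals above the floor. Windows of 25 genes gave 2 higher and 5 lower runs, where windows of 50 gave 4 and 10, and the cause was not tested. Leaving out genes of shifted runs gave no value for the list of ABCB1 neighbours and left 1 histone gene 2-fold higher, of 9. Signals near the floor limit all bounds.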

Other observations

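The gene families below, and the tests of another cell line and of admixed fibroblasts, were chosen after the values were seen, whereas the remaining tests were set before their result was seen. Of 16 measured serpins, 10 were at least 2-fold higher and 2 lower, among them the protease inhibitors SERPINA5 (16.8-fold) and SERPINA3 (13.7-fold), with a family median between 0.81 and 1.99 over the alternatives. Of 20 collagen genes 11 were higher and 0 lower. The basement membrane chains COL4A5 and COL4A6, which neighbour each other in the genome, were at least 47.7-fold and at least 40.8-fold higher, COL5A2 10.2-fold and COL6A1 10.2-fold. All 3 measured trefoil factors, secreted with mucus in the gut, were higher, TFF1 7.42-fold and TFF3 at least 30.8-fold. Mucins were higher in 5 of 8 and lower in 0, with MUC5B 5.84-fold and MUC13 3.25-fold higher. Golgi trafficking genes of the YIPF and TMED families were higher in 7 of 15 and lower in 0, led by YIPF2 at 10.2-fold.

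All 4 ID genes, targets of BMP signalling, were lower in hepatospheres: ID1 2.06-fold, ID2 2.97-fold, ID3 2.2-fold and ID4 at least 33.8-fold. Nucleolar ribosome assembly factors were lower in 13 of 31 and higher in 0 (median -0.85), with UTP20 4.85-fold and NOP14 3.36-fold lower, while the ribosomal protein genes themselves stayed within 2-fold. Nucleoporins were lower in 8 of 21 and higher in 1, with NUP50 4.04-fold lower and NUP58 2.70-fold higher on its brightest probe set, which its other 2 probe sets contradict. The medians of these families kept their sign under all 11 alternatives, relative to the all-gene median under poly(A) scaling. Genes of the MAGE family, pooled by name across its subfamilies, showed no such direction (5 higher and 3 lower of 14, with a median that changed sign under 2 alternatives). The 3 lower genes were MAGEA4, MAGEA10 and MAGEB2 (7.12-fold), whereas MAGED1, MAGED2 and MAGEH1 (3.41-fold) were among the 5 higher. The subfamilies were not summarised apart.

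Neighbouring genes around ABCB1 read higher together on the hepatosphere array. Relative to the all-gene median the brighter genes of the run stood at 0.63 and its dimmer genes at 0.63. The run stood at 0.65 after loess, and its other probe sets at 0.74 against all other probe sets. The shift was thus not confined to dim genes or to the chosen probe sets, and was not removed with the trend in signal. These genes were chosen for high window medians on the same arrays, so the values are partly built in and do not exclude noise of low signals. The lower of the medians before and after ABCB1, 0.57, decides nothing about gene copies, because the run was chosen for high window medians. More copies of this stretch in the hepatosphere cells thus stay an open hypothesis: DNA was not measured here, the shift was uneven (0.99 in the window from CD36 to SDHAF3, 0.68 in that from STEAP1 to TMEM225B), and ABCB1 itself stands at 3.92. Another cell line or a mixed sample on 1 array cannot be told apart from these, since the correlation of 0.89 across genes has no reference value from repeated arrays.

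LUM, COL3A1, S100A4, TIMP1 and LGALS1 read higher on the hepatosphere array, a set that fibroblasts express too. Of 6 abundant fibroblast transcripts 0 reached 1000 on that array. That bound was set after the values were seen, and COL3A1 misses it too, at 679. COL1A2, COL6A3 and PDGFRB lay below the floor at 35.6, 3.72 and 66.9 while LUM read 2677. This argues against admixed fibroblasts rich in COL1A2 and COL6A3. Signals of different probe sets share no common scale, so these levels do not exclude admixture. COL1A1, DCN and SPARC, which did reach the floor, read higher than in differentiated cells. Other matrix genes that fibroblasts express were higher too, COL5A2 from 470.2 to 4795, COL6A1 from 85.6 to 870.1 and LOX from 399 to 1395, and count in favour of admixture. Leukocyte and endothelial markers taken without a floor had a median difference of 0.17 over 31 genes, LYZ and PECAM1 among them at high signals. This argues against a shift of all low signals as large as the differences of LUM and COL3A1. A smaller shift stays open. The median signal was 84.1 on the hepatosphere array and 70.6 on the other. Only the hepatosphere array had 1262 genes at the floor or above, and only the other had 441. Expression in the hepatosphere cells themselves stays a hypothesis, found and tested on the same 2 arrays, on which the culture conditions are not separated.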
